A study of Mus musculus with 6 samples.

How the data were processed

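The study measured messenger RNA of mouse splenic plasmacytoid dendritic cells by deep sequencing on an Illumina HiSeq system. Per the submitters, RNA was extracted with Trizol and libraries were made with the VAHTS mRNA-seq v2 kit after stimulation for 12 hours. The titles place 3 libraries in the R837 group and 3 in the R837 plus taurine group. Nothing states that the replicates came from separate animals or cultures, so p-values that compare libraries measure only the spread between these libraries, whatever its source. Every pair of libraries of one group differed by more than sampling noise, so none was counted as a repeat of another.

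Each deposited file gives a signal value per gene, called a normalized count per the file headers. Every value was a whole multiple of 1 step per library, to within 0.001 of a whole read for 100% of values. The authors therefore deposited whole reads divided by 1 size factor per library, and the factors lay between 0.942 and 1.06. HISAT2, StringTie and the builds mm8 and mm10 are named in the submitters' processing notes, with no role, order or version. The tool that counted reads, its strand setting and the normalizing tool are not given in the sources used here. Of the 52403 gene identifiers shared with GENCODE release M21 (mm10), 95.2% had the same coordinates in both, so the coordinates printed are taken as mm10. Without a known strand setting, reads of a gene and of an overlapping or antisense gene cannot be told apart, and near-identical copies share reads, so such genes are given as uncertain. Sums with overlapping genes take in all reads of each such gene, however small the overlap and on either strand. They can therefore reflect the other gene's own level, and a changed value alone does not show that reads moved. Exon overlap, exon length (union of annotated exons), GC content (longest transcript) and biotype came from GENCODE M21, which matched 99.8% of tested genes. For 27 genes the symbol stood as a day number, and these took the symbol of their gene identifier. The 37 mitochondrially encoded genes were listed at 0 in every library, so the list of such genes fixed beforehand was not tested.

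Recovered reads on genes came to between 33585080 and 38392654 per library. Tests used log2(normalized count + 1) of the 15265 genes with a normalized count of at least 10 in at least 3 of the 6 libraries, whatever their group. The pseudocount of 1 draws the values of genes with few reads together. A single library at 0 can still enlarge their log2 change, as for Ifna1 with 0 in R837 replicate 2, so such changes are not all understated. A linear model with 1 group term was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an abundance trend in the prior variance, two-sided, with Benjamini-Hochberg adjustment over all tested genes, and an adjusted p under 0.05 was a call. FPKM values had been assumed before the data were examined, with a floor of 1 in 3 libraries, a stricter floor of 5 and a floor of 3 for named genes. The floors of 10, of a mean of 50 and of a mean of 100 replaced these once the unit was known and before any test was run. As a check of the unit, edgeR 4.0.16 (quasi-likelihood test, TMM, filterByExpr) was run on the recovered reads and called 950 genes, of which 934 were among the 979 of limma. It was chosen after seeing the data, as were the use of DESeq2 1.42.0, the removal of length and GC trends and the restriction to genes whose exons overlap no other gene. To remove these trends, a smooth curve on log exon length and GC content was taken from each library's deviations from the gene means.

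The 29 gene lists were fixed before the data were examined and cover the interferon, TLR, cytokine, antigen presentation, taurine, stress, metabolic and cell type groups named in the results. The 28 lists with at least 5 tested members were tested with camera from limma (preset inter-gene correlation 0.01, Benjamini-Hochberg over the lists), which compares a list with all other genes. With the preset correlation its p-values rest on the number and spread of genes, so they do not measure the spread between libraries. The alternative fry tests a list against no change, and ranges of adjusted p over the other alternatives include it. With an estimated correlation, only the interferon-stimulated and the cholesterol and fatty acid lists passed. Some genes are in more than 1 list: 2 members of the cytokine list and 3 of the antigen presentation list are also in the interferon-stimulated list, and both lists still passed without them. The naming rules took the 12 genes with the largest rise and the 12 with the largest fall among called genes with non-overlapping groups, a mean of at least 100 in the higher group and a symbol that is not a predicted or clone name. They also took up to 4 members with the smallest p of each list described, and a fixed set of 16 genes (Tlr7, Myd88, Irf7, Irf5, Ifnb1, Ifna4, Isg15, Cxcl10, Il6, Tnf, Il12b, Siglech, Bst2, Slc6a6, Csad and Cdo1).

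The model was tested on simulated data: negative binomial counts for the 15265 tested genes with the libraries' sizes and the genes' means and dispersions, 200 of them changed, in 10 simulations. It called 31.5% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 98.3% of those changed 4-fold. All changed genes were drawn from those with a mean above 100, so these shares do not describe genes with fewer reads. False calls made up 7.50% of calls, above the nominal 5%. With no change simulated it called 0 genes and 0 lists, and a list shifted by 0.4 on the log2 scale was called with a median of 0.39 and 0 other lists. Each of these cases was a single simulation with every gene drawn on its own. They therefore cannot show how often lists of correlated genes are called falsely. The alternatives covered the pseudocount, the filter, library scaling, the variance prior, a term for replicate number, each library left out, the list test and the count models. A planned comparison with TPM was not run, since the files hold normalized counts. Figures were drawn with matplotlib 3.10.9.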

Results

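Messenger RNA was sequenced from plasmacytoid dendritic cells of the spleen of C57BL/6 mice. These cells sense nucleic acids through the endosomal receptors TLR7 and TLR9 and answer with type I interferon. All samples received R837 (imiquimod), a small-molecule agonist of TLR7, for 12 hours. In 3 libraries R837 was given alone, and in the other 3 it was given together with taurine, an amino sulfonic acid that cells take up through the transporter Slc6a6. The comparison asks how the transcripts of TLR7-stimulated cells differ when taurine is present. Libraries without R837 were not analysed here, so every value describes stimulated cells. The files held a normalized count for each of 52550 genes, from which whole reads were recovered. R837 replicates 1, 2 and 3 held 37848601, 36764444 and 33585080 reads on genes, and taurine replicates 1, 2 and 3 held 36174132, 38392654 and 34449848. Between 18739 and 19003 genes had a value above 0 in a library, and the 10 most abundant genes took 4.71% to 5.50% of the reads. Levels are mean normalized counts ± SD with n = 3 libraries per group. Changes are on the log2(normalized count + 1) scale, R837 plus taurine minus R837, with adjusted p-values from limma, and coordinates are those of the files on mm10.

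Libraries of the same group correlated with Pearson's r of 0.963 to 0.969 across genes, and libraries of different groups with 0.956 to 0.964. Genes are not independent replicates in these coefficients. The leading principal component carried 29.0% of the variance and placed the R837 libraries between -47.6 and -12.8 and the taurine libraries between 29.6 and 43.5. R837 replicate 3, at -12.8, lay nearest to the other group. The Spearman correlation of a library's deviations with exon length was 0.188, 0.244 and 0.114 in R837 replicates 1, 2 and 3, and -0.122, -0.158 and -0.291 in the taurine replicates. Of 15265 genes tested, 573 were higher and 406 lower with taurine at an adjusted p under 0.05 (limma with trend, Benjamini-Hochberg), which is 6.41% of those tested. The changes were mostly small, with a median absolute log2 change of 0.50 among these genes. A log2 change of at least 1 was reached by 33 of the higher and 44 of the lower genes. All 3 libraries of one group lay above all 3 of the other for 29.6% of tested genes, where chance gives 10%. When library totals were rescaled without the 50 most abundant genes, 462 genes were higher and 586 lower, so the share of higher genes fell from 58.5% to 44.1%. The number past the threshold depended on single libraries: it was 326, 134 and 1477 without R837 replicate 1, 2 or 3, and 318, 250 and 153 without taurine replicate 1, 2 or 3. limma without the abundance trend in its variance prior passed only 4 genes, while 3217 had an unadjusted p under 0.05; edgeR on the recovered reads passed 950 and DESeq2 1842.

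Interferon-stimulated genes rose as a group with taurine. Of 67 measured members of the list, 38 were higher and 0 lower, or 48 and 0 when adjusted over the list alone, and the median log2 change was 0.41. Cxcl10, a chemokine that draws activated T cells (ENSMUSG00000034855.13, chromosome 5, 92346638 to 92348889, minus strand), went from 16868 ± 1675 to 31958 ± 1649 (log2 change 0.93 ± 0.08 (SE), adjusted p = 0.00286). Cmpk2, a mitochondrial nucleotide kinase induced by interferon (ENSMUSG00000020638.8, chromosome 12, 26469204 to 26479837, plus strand), went from 5682 ± 433 to 10456 ± 153 (log2 change 0.88 ± 0.07 (SE), adjusted p = 0.00238). The antiviral GTPase gene Mx1 (ENSMUSG00000000386.14, chromosome 16, 97447035 to 97462907, minus strand) rose from 39652 ± 607 to 58188 ± 679.9 (log2 change 0.55 ± 0.05 (SE), adjusted p = 0.00286). Irf7, the transcription factor that drives interferon alpha expression in these cells (ENSMUSG00000025498.15, chromosome 7, 141262706 to 141266481, minus strand), rose from 23976 ± 908 to 37645 ± 1797 (log2 change 0.65 ± 0.06 (SE), adjusted p = 0.00296). The ubiquitin-like modifier Isg15 rose by 0.61 ± 0.06 (SE, adjusted p = 0.00370). Ifitm2 had a log2 change of 1.13, but 0.21 with the reads of overlapping genes added, so its rise is uncertain. Each of the 5 genes from Cxcl10 to Isg15 was higher in all 3 taurine libraries than in any R837 library and kept its call with any 1 library left out. The list passed camera with an adjusted p of 5.60e-28, and with an adjusted p = 0.0294 with an estimated correlation. Over the other alternatives the adjusted p ran from 5.44e-34 to 0.000376. The number of members past the threshold was 24, 17 and 42 without R837 replicate 1, 2 or 3, and 24, 22 and 16 without taurine replicate 1, 2 or 3. After removal of each library's trend on exon length and GC content the list median was 0.43.

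**Figure D1:**
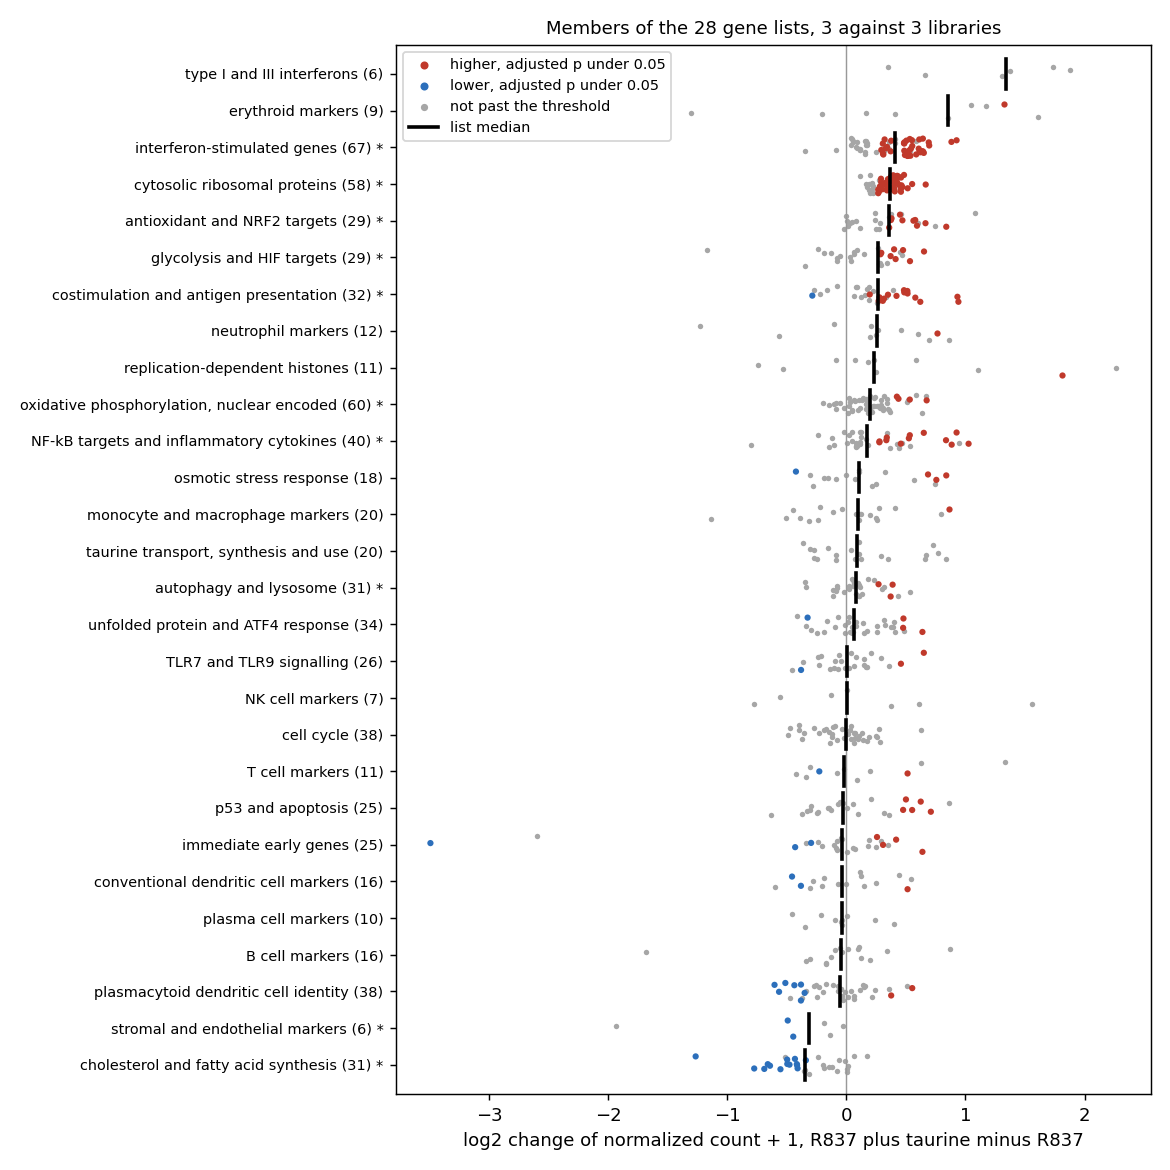
Each point is a gene, placed by its log2 change (R837 plus taurine minus R837, 3 against 3 libraries) on the line of its list, with the number of measured members in parentheses, the list median as a black bar and an asterisk for lists with a camera adjusted p under 0.05. The medians of the interferon-stimulated and ribosomal protein lists lie at 0.41 and 0.37, and that of the cholesterol and fatty acid list at -0.35.

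The interferon transcripts themselves were scarce at 12 hours. The 20 listed type I and type III interferon genes together took 210, 180 and 151 reads in the R837 replicates and 292, 301 and 248 in the taurine replicates. This is 4.50 to 5.55 CPM against 7.20 to 8.07. The summed interferon alpha genes had a normalized count of 58.0 ± 30.7 with R837 and 130.2 ± 33.3 with taurine (SD, n = 3), and a two-sided exact permutation test gave p = 0.2, where 0.1 is the smallest p that 3 against 3 allows. None of the 6 members past the filter was called (0 of 6 also when adjusted over the list alone), and the list did not pass (median log2 change 1.34, camera adjusted p = 0.0861). Ifna5, Ifna2, Ifna6 and Ifna1 had log2 changes of 1.30, 1.37, 1.88 and 1.74 with adjusted p-values of 0.246, 0.309, 0.347 and 0.387. These genes are near-identical copies, so their single values are uncertain. Ifna4 stayed below the filter, with 22, 0 and 4 reads with R837 and 4, 8 and 9 with taurine. Without R837 replicate 2 Ifna6 and Ifna1 had 0.67 and 0.40, and without taurine replicate 2 Ifna2 had 2.17. Ifnb1 had 91.0 ± 7.47 to 119 ± 34.1 (log2 change 0.35, adjusted p = 0.475), with 0.16 and 0.59 without taurine replicate 2 or 3. The list passed without a filter on low values (adjusted p = 0.0332), where more members entered. The adjusted p was 0.289 with an estimated correlation and ran from 0.0102 to 0.190 over the other alternatives.

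The receptors and adaptors of the TLR7 pathway did not move as a group: of 26 members 2 were higher and 1 lower (2 and 3 adjusted over the list alone), with a median log2 change of 0.01 and a camera adjusted p of 0.756. Besides Irf7, the adaptor Myd88 rose (3436 ± 136 to 4738 ± 515, log2 change 0.46, adjusted p = 0.0281). The kinase Irak1 fell (3649.9 ± 70.3 to 2803 ± 45.4, log2 change -0.38, adjusted p = 0.0205), and the ubiquitin ligase Traf3 had log2 change -0.46, adjusted p = 0.0543. Tlr7 had 11987 ± 6652 to 14103 ± 2287 (log2 change 0.36, adjusted p = 0.532) and Irf5 10435 ± 263 to 10739 ± 155 (log2 change 0.04, adjusted p = 0.720), neither past the threshold. Tlr7 rested on single libraries, with 0.78, 0.0776 and 0.21 without R837 replicate 1, 2 or 3. The NF-kB and inflammatory cytokine list rose: 12 of 40 members were higher and 0 lower (15 and 0 adjusted over the list alone), with a median log2 change of 0.17 and a camera adjusted p of 2.00e-07 (adjusted p = 0.228 with an estimated correlation, and 2.22e-08 to 0.00978 over the other alternatives). Besides Cxcl10, its leading members were the chemokine genes Ccl5 (24962 ± 1840.1 to 35888 ± 2036, log2 change 0.52, adjusted p = 0.00787) and Ccl4 (35855 ± 2579 to 45297 ± 643, log2 change 0.34, adjusted p = 0.0204). Cxcl11 was also among them (521 ± 148 to 1035 ± 31.5, log2 change 1.03, adjusted p = 0.0198), but GENCODE M21 lists it as a polymorphic pseudogene. Its rise is therefore not read as that of a working chemokine. Il12b, a subunit of interleukin 12 and 23, rose from 48926 ± 1287 to 59330 ± 2878 (log2 change 0.28, adjusted p = 0.0271). Myd88, Irak1, Ccl5, Cxcl11, Ccl4 and Il12b kept their calls in 2, 1, 6, 3, 2 and 1 of the 6 fits with 1 library left out. Tnf (26571 ± 3523 to 27275 ± 699, log2 change 0.05, adjusted p = 0.807) and Il6 (8424 ± 2223 to 10688 ± 1078, log2 change 0.37, adjusted p = 0.215) did not pass. Il6 had 0.22 and 0.57 without R837 replicate 1 or 3. The median of this list lay at percentile 83.8 of 10000 random lists matched on expression, exon length and GC content, and exons of Cxcl11 overlap another gene, so its reads are uncertain.

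Genes of dendritic cell maturation and antigen presentation rose with taurine by the preset test, though the list did not pass with an estimated correlation (adjusted p = 0.228). Of 32 members, 15 were higher and 1, the class II transactivator Ciita, was lower (log2 change -0.29, a gene looked up after its value was seen); adjusted over the list alone the numbers were 21 and 1. Fscn1, the actin-bundling protein of mature dendritic cells (ENSMUSG00000029581.14, chromosome 5, 142960343 to 142973185, plus strand), showed 52409 ± 5525 to 99758 ± 4513 (log2 change 0.93 ± 0.08 (SE), adjusted p = 0.00238). Ccr7, the receptor that guides mature dendritic cells to lymph nodes (ENSMUSG00000037944.8, chromosome 11, 99144196 to 99155077, minus strand), showed 95821 ± 3594 to 136930 ± 8345 (log2 change 0.51 ± 0.06 (SE), adjusted p = 0.00493). The immunoproteasome subunits Psmb8 (5506 ± 199 to 8475 ± 517, log2 change 0.62, adjusted p = 0.00509) and Psmb10 (2178 ± 278 to 4184 ± 541, log2 change 0.94, adjusted p = 0.00675) rose as well. Cd40 and Cd274 (PD-L1) rose by 0.51 and 0.27, both looked up after their values were seen. Fscn1, Ccr7, Psmb8 and Psmb10 kept their calls with any 1 library left out. The list median was 0.26 with a camera adjusted p of 2.08e-11 (2.96e-12 to 0.0102 over the other alternatives). After removal of the length and GC trends the median was 0.17.

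Several transcripts that mark plasmacytoid dendritic cells fell, while the marker list as a whole did not pass. Of 38 members 2 were higher and 7 lower (5 and 10 adjusted over the list alone), the median log2 change was -0.06 and the camera adjusted p was 0.144. Runx2, a transcription factor needed for the exit of these cells from bone marrow (ENSMUSG00000039153.16, chromosome 17, 44495987 to 44814797, minus strand), fell from 14375 ± 363 to 9466 ± 450.2 (log2 change -0.60 ± 0.06 (SE), adjusted p = 0.00415). Tcf4 (E2-2), the factor that specifies and maintains the lineage (ENSMUSG00000053477.16, chromosome 18, 69343356 to 69689079, plus strand), fell from 16402 ± 1799.8 to 11452 ± 269 (log2 change -0.51 ± 0.08 (SE), adjusted p = 0.0137). Pacsin1 (4234 ± 105 to 3252 ± 107, log2 change -0.38, adjusted p = 0.0206) and Rpgrip1 (7312 ± 625 to 4929 ± 89.9, log2 change -0.57, adjusted p = 0.00942) also fell, the latter with exons that overlap Supt16 and a log2 change of -0.33 with the reads of that gene added. The higher members were Bst2 (tetherin), which interferon induces (39427 ± 2427 to 51217 ± 4041, log2 change 0.38, adjusted p = 0.0240), and Cox6a2 (log2 change 0.55), looked up after its value was seen. Siglech, the surface marker most used for these cells, stood at 11769.6 ± 1434 to 11361 ± 889 (log2 change -0.05, adjusted p = 0.820). Runx2 kept its call with any 1 library left out, and Tcf4, Pacsin1, Rpgrip1 and Bst2 kept theirs with 2, 1, 5 and 2 of the 6 left out. The list passed under quantile normalization (median -0.11, adjusted p = 0.00782), after removal of the length and GC trends (median -0.13, adjusted p = 0.0449) and with fry, which tests a list against no change and not against other genes (adjusted p = 0.00978). The adjusted p was 0.298 with an estimated correlation and ran from 0.00782 to 0.326 over the other alternatives. The median ran from -0.0926 to -0.0516 with 1 library left out.

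Markers of other spleen cells were measured beside these. None of the following lists passed camera: B cells (0 higher and 0 lower of 16, 1 and 1 adjusted over the list alone, median log2 change -0.05, adjusted p = 0.775), plasma cells (0 higher and 0 lower of 10, 0 and 0 adjusted over the list alone, median log2 change -0.04, adjusted p = 0.393), T cells (1 higher and 1 lower of 11, 1 and 2 adjusted over the list alone, median log2 change -0.02, adjusted p = 0.966), NK cells (0 higher and 0 lower of 7, 0 and 0 adjusted over the list alone, median log2 change 0.00, adjusted p = 0.966) and conventional dendritic cells (1 higher and 2 lower of 16, 1 and 3 adjusted over the list alone, median log2 change -0.04, adjusted p = 0.654). The same held for monocytes and macrophages (1 higher and 0 lower of 20, 2 and 1 adjusted over the list alone, median log2 change 0.09, adjusted p = 0.669), neutrophils (1 higher and 0 lower of 12, 2 and 0 adjusted over the list alone, median log2 change 0.26, adjusted p = 0.179) and erythroid cells (1 higher and 0 lower of 9, 2 and 0 adjusted over the list alone, median log2 change 0.85, adjusted p = 0.179). With 1 library left out the median ran 0.00112 to 0.50 for neutrophils (lowest without R837 replicate 2, highest without R837 replicate 1), 0.46 to 1.05 for erythroid cells (without R837 replicates 1 and 3), 0.00488 to 0.14 for monocytes and macrophages (without R837 replicates 2 and 3) and -0.15 to -0.0145 for B cells. For T cells the test leaned upward while the median lay below 0. The single calls were Ccr7 and Cd8a (log2 change -0.23) among T cell markers, and Clec9a (-0.46), Flt3 (-0.38) and Ccr7 among conventional dendritic cell markers. Fcgr1, an interferon-inducible Fc receptor (0.86), Ngp (0.76) and the near-duplicated globin gene Hba-a1 (1.33, from 34.4 ± 7.28 to 87.8 ± 19.1) were the single calls among macrophage, neutrophil and erythroid markers. The stromal and endothelial list fell (camera adjusted p = 0.0197, median -0.32, 0 higher and 2 lower of 6, the same numbers adjusted over the list alone; adjusted p = 0.433 with an estimated correlation, and 0.00351 to 0.192 over the other alternatives). Its members past the threshold were Kdr, a receptor for vascular endothelial growth factor (68334 ± 6419 to 50025 ± 1764, log2 change -0.45, adjusted p = 0.0145), and Cdh5, endothelial cadherin (16474 ± 1593 to 11677 ± 399.7, log2 change -0.49, adjusted p = 0.0136). Kdr and Cdh5 kept their calls in 2 and 3 of the 6 fits with 1 library left out. Without R837 replicate 3 the median of this list was -0.48, and without a filter on low values the list did not pass (adjusted p = 0.148). The median lay at percentile 5.50 of the random lists matched on expression, length and GC.

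Genes of cholesterol and fatty acid synthesis fell together. Of 31 members 14 were lower and 0 higher (16 and 0 adjusted over the list alone), with a median log2 change of -0.35. Scd2, a stearoyl-CoA desaturase (ENSMUSG00000025203.5, chromosome 19, 44293676 to 44306864, plus strand), fell from 15083 ± 1267 to 8812 ± 599 (log2 change -0.77 ± 0.08 (SE), adjusted p = 0.00427). Lss, lanosterol synthase (ENSMUSG00000033105.12, chromosome 10, 76531588 to 76557138, plus strand), fell from 9567 ± 185 to 5945 ± 485 (log2 change -0.69 ± 0.08 (SE), adjusted p = 0.00443). The sterol enzyme gene Hsd17b7 fell from 6833 ± 385 to 4376 ± 88.0 (log2 change -0.64, adjusted p = 0.00443) and the sterol carrier gene Stard4 from 4020.1 ± 190.2 to 2545 ± 164 (log2 change -0.66, adjusted p = 0.00636). The fatty acid elongase gene Elovl6 had the largest fall of the list, from 634 ± 52.1 to 266 ± 51.5 (log2 change -1.27, adjusted p = 0.00727). These 5 kept their calls with any 1 library left out. The list passed camera with an adjusted p of 2.61e-11, with an adjusted p = 0.0468 with an estimated correlation, and with 4.83e-14 to 0.000662 over the other alternatives. The number of its members past the threshold was 11, 6 and 15 without R837 replicate 1, 2 or 3, and 10, 10 and 7 without taurine replicate 1, 2 or 3.

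**Figure D2:**
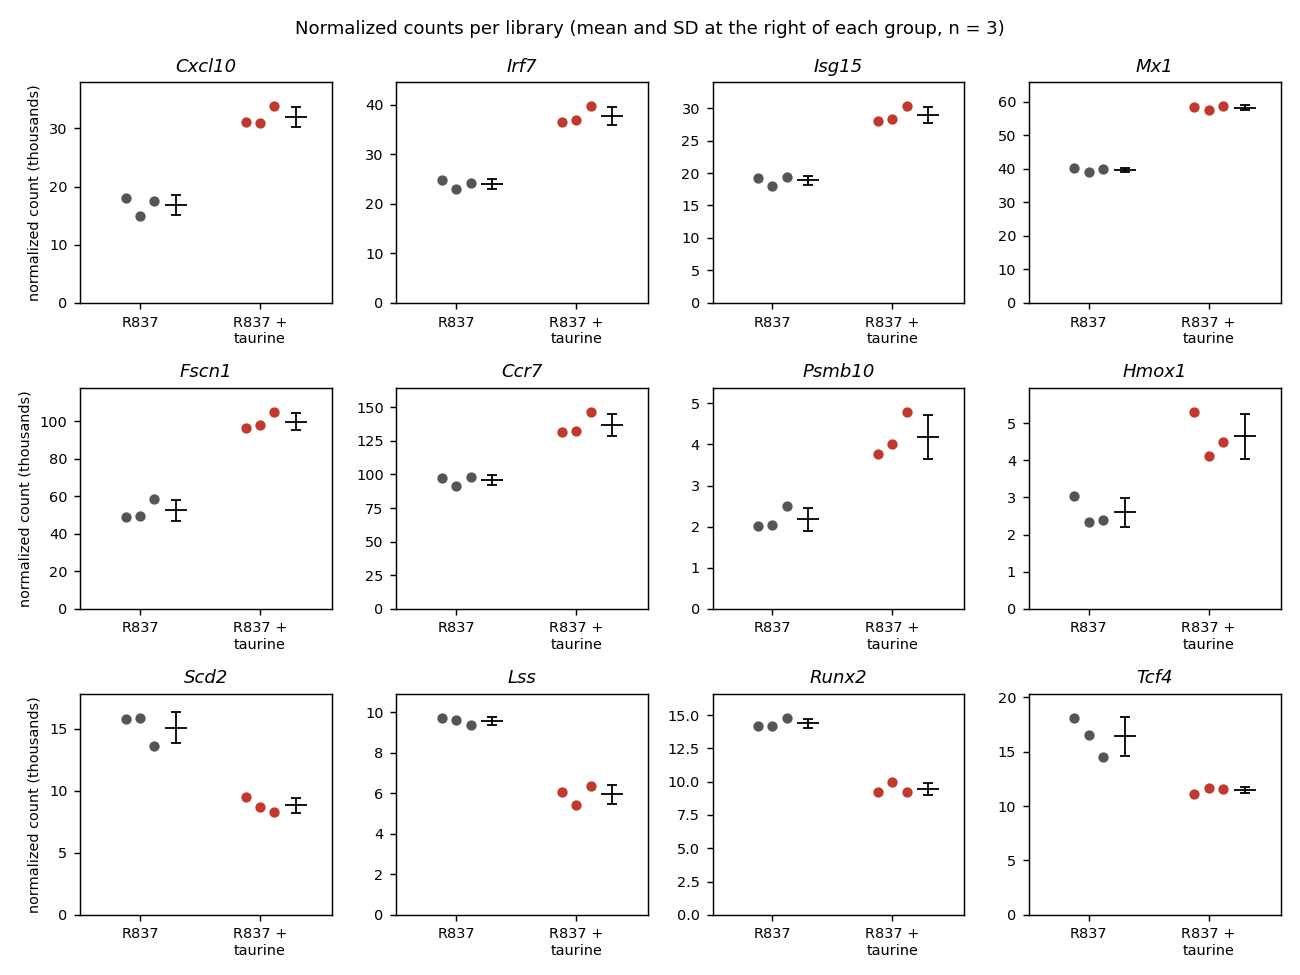
Normalized counts divided by 1000 (vertical axes from 0) of 12 genes in each of the 3 R837 libraries (grey points) and 3 R837 plus taurine libraries (red points), with the mean and SD of each group as a bar to its right. In every panel the 3 libraries of one group lie apart from the 3 of the other, as for Cxcl10 (16868 ± 1675 against 31958 ± 1649) and Scd2 (15083 ± 1267 against 8812 ± 599).

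Ribosomal protein genes rose with taurine by the preset test but not with an estimated correlation (adjusted p = 0.228), and they moved together with a trend on transcript length. Of 58 cytosolic ribosomal protein genes, 45 were higher and 0 lower (56 and 0 adjusted over the list alone), with a median log2 change of 0.37 and a camera adjusted p of 2.63e-32 (2.83e-37 to 0.00978 over the other alternatives). Rpl12 rose from 8163 ± 124 to 10989.9 ± 494 (log2 change 0.43, adjusted p = 0.0112). Rpl6 rose by 0.43 (adjusted p = 0.0120) and Rpl24 by 0.67 (adjusted p = 0.00675), the last with exons that overlap another gene model and a log2 change of 0.35 with its reads added. Ribosomal protein genes have many processed pseudogenes, so their reads are uncertain. The number of members past the threshold was 14, 2 and 43 without R837 replicate 1, 2 or 3, and 20, 7 and 4 without taurine replicate 1, 2 or 3. Of 60 nuclear-encoded oxidative phosphorylation genes only 4 were higher and 0 lower (11 and 0 adjusted over the list alone), namely Uqcrq (log2 change 0.67, adjusted p = 0.00675), Cox4i1 (log2 change 0.42, adjusted p = 0.0273), Atp5o (log2 change 0.44, adjusted p = 0.0341) and Ndufb7 (log2 change 0.53, adjusted p = 0.0428). Their list median was 0.20 (camera adjusted p = 4.20e-08, adjusted p = 0.228 with an estimated correlation, and 2.80e-10 to 0.0137 over the other alternatives). Uqcrq, Cox4i1, Atp5o and Ndufb7 kept their calls in 6, 2, 1 and 1 of the 6 fits with 1 library left out. Genes with short exon length tended upward with taurine and those with long exon length downward. Among 11959 genes with a mean of at least 50, the median log2 change was 0.15 in the fifth with the shortest exon length and -0.13 in the fifth with the longest. Called genes were 205 higher and 33 lower in the former, and 39 higher and 195 lower in the latter. Median exon length was 2773 nt for all higher and 7204.5 nt for all lower genes. The Spearman correlation across the genes with a mean of at least 50 was -0.278 with exon length and 0.174 with GC content. With that trend removed, 595 genes were higher and 341 lower, of which 710 were among the 979 called before. The median log2 change was then 0.25 for ribosomal proteins (32 of 58 higher) and 0.11 for oxidative phosphorylation (3 of 60 higher).

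**Figure D3:**
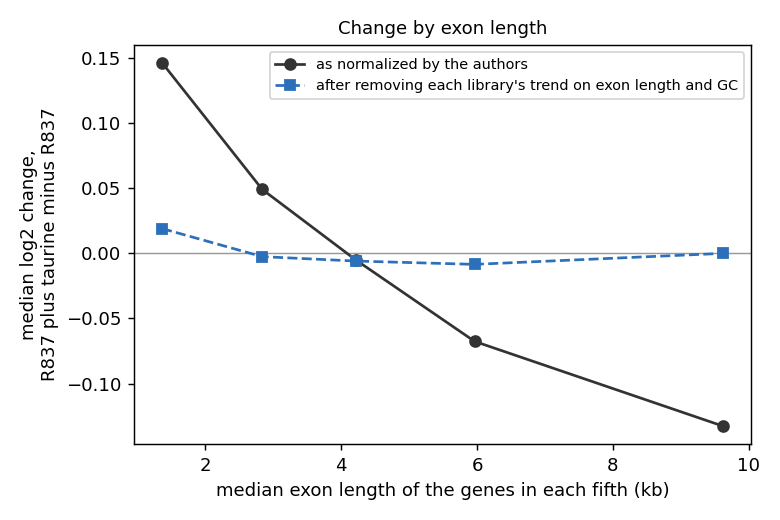
Median log2 change (R837 plus taurine minus R837, vertical axis) of genes in 5 equal groups by exon length, placed at the median exon length of each group in kb, as normalized by the authors (black) and after removing each library's trend on exon length and GC content (blue). The black medians run from 0.15 for the shortest to -0.13 for the longest genes, and the blue medians lie between -0.01 and 0.02.

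Glycolysis and HIF target genes rose in 8 of 29 members, with 0 lower (11 and 1 adjusted over the list alone). Enolase Eno1 went from 3054 ± 101 to 4423 ± 116 (log2 change 0.53, adjusted p = 0.00747), Pfkfb3 from 5502 ± 148 to 7664 ± 529 (log2 change 0.48, adjusted p = 0.0123). Pfkp rose by 0.40 (adjusted p = 0.0153) and pyruvate kinase Pkm by 0.37 (adjusted p = 0.0153). The list median was 0.27 (camera adjusted p = 0.000713, adjusted p = 0.128 with an estimated correlation, and 0.000127 to 0.195 over the other alternatives). It was 0.07 (adjusted p = 0.195) among genes whose exons overlap no other gene, and 0.18 without R837 replicate 1. Antioxidant and NRF2 target genes rose in 10 of 29 members with 0 lower (13 and 0 adjusted over the list alone), with a median log2 change of 0.36 and a camera adjusted p of 2.22e-09 (adjusted p = 0.228 with an estimated correlation, and 3.73e-12 to 0.0150 over the other alternatives). Heme oxygenase Hmox1 rose from 2598 ± 391 to 4641 ± 601 (log2 change 0.84, adjusted p = 0.0121), the ferritin light chain Ftl1 from 139673 ± 10113 to 221121 ± 8925 (log2 change 0.66, adjusted p = 0.00299). Superoxide dismutase Sod1 rose by 0.45 (adjusted p = 0.00691) and thioredoxin Txn1 by 0.56 (adjusted p = 0.0136). Exons of Ftl1 overlap other gene models, so its level is uncertain. Of 31 autophagy and lysosome genes 3 were higher and 0 lower, the same adjusted over the list alone: the autophagy receptor Sqstm1 (34983 ± 897 to 45788 ± 1093, log2 change 0.39, adjusted p = 0.00748), Gabarap (log2 change 0.37, adjusted p = 0.0196) and the protease Ctsz (log2 change 0.27, adjusted p = 0.0292). Map1lc3a had log2 change 0.43, adjusted p = 0.0726. That list passed with a median of 0.08 (camera adjusted p = 0.0225, adjusted p = 0.298 with an estimated correlation, and 0.00806 to 0.106 over the other alternatives). It no longer passed without R837 replicate 3 (adjusted p = 0.0821) or without taurine replicate 3 (adjusted p = 0.0600). The same held under quantile normalization (0.0506), rescaling without the 50 most abundant genes (0.0561), limma without trend (0.0516), fry (0.0545) and among genes without exon overlap (0.106), so it passed in 15 of 22 other alternatives. Its median lay at percentile 84.9 of the matched random lists.

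Genes that handle taurine showed no call. Of 20 genes for its transport, synthesis and use, 0 were higher and 0 lower, also when adjusted over the list alone, with a median log2 change of 0.09 (camera adjusted p = 0.522) and medians of 0.0299 to 0.13 with 1 library left out. The taurine transporter gene Slc6a6 was abundant, at 16139.8 ± 541 to 17369.7 ± 547 (log2 change 0.11, adjusted p = 0.322). The synthesis genes Csad (65.8 ± 32.9 to 77.7 ± 32.4, log2 change 0.29, adjusted p = 0.753) and Cdo1 (12.0 ± 3.08 to 23.2 ± 9.05, log2 change 0.83, adjusted p = 0.414) were low. Gadl1, Ggt5, Trmu and Mto1 had the smallest p-values of the list, with log2 changes of 0.72, 0.77, 0.35 and -0.25 and adjusted p-values of 0.0926, 0.220, 0.253 and 0.319. In the osmotic stress list (3 higher and 1 lower of 18, the same adjusted over the list alone, median 0.11, adjusted p = 0.0609), the heat shock genes Hspa1b (12909.8 ± 509 to 21793 ± 609, log2 change 0.76, adjusted p = 0.00238) and Hspa1a (11836 ± 582 to 19031 ± 662, log2 change 0.69, adjusted p = 0.00296) and Hmox1 rose, and the amino acid transporter Slc38a2 fell (20955 ± 532 to 15628 ± 629.6, log2 change -0.42, adjusted p = 0.00905). Hspa1a and Hspa1b are near-identical copies whose reads cannot be fully parted. This list passed without R837 replicate 2 (adjusted p = 0.0361) or taurine replicate 1 (adjusted p = 0.0382), and had an adjusted p = 0.228 with an estimated correlation. It passed in 7 of 22 other alternatives, with 0.00103 to 0.195 over them and medians of 0.0667 to 0.15 with 1 library left out. The unfolded protein and ATF4 list did not pass (3 higher and 1 lower of 34, 6 and 4 adjusted over the list alone, median 0.07, adjusted p = 0.0846): Syvn1 (0.48), Atf3 (0.64) and Ddit3 (0.48) rose and Herpud1 (-0.33) fell. With all reads of overlapping genes added Ddit3 had 0.20. No single gene overlaps more than 3.97% of its exon length, so this sum does not decide whether its own rise holds. The list passed without R837 replicate 2 (adjusted p = 0.0447) or taurine replicate 1 (adjusted p = 0.0378), and had an adjusted p = 0.298 with an estimated correlation. Of the other alternatives it passed 6 of 22, with 0.0268 to 0.537 over them and medians of 0.0579 to 0.12 with 1 library left out.

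Among p53 and apoptosis genes, 5 of 25 were higher and 0 lower (7 and 1 adjusted over the list alone). Among the higher ones were the cell cycle inhibitor Cdkn1a (13529 ± 642 to 19136 ± 789.9, log2 change 0.50, adjusted p = 0.00675), Bak1 (0.48) and the death receptor Fas (0.71). The list as a whole did not pass, with a median of -0.03 below 0, a mean of 0.07 and a test that leaned upward (adjusted p = 0.235). The adjusted p was 0.371 with an estimated correlation. Over the other alternatives it ran from 0.00978 to 0.439, under the threshold only with fry, which tests against no change. The cell cycle list did not pass either (0 higher and 0 lower of 38, also adjusted over the list alone, median -0.01, adjusted p = 0.669), and its member with the smallest p, Cenpf, had log2 change -0.49, adjusted p = 0.0610. Of 11 tested genes in the replication-dependent histone list only Hist1h4d was called (23.4 ± 5.62 to 84.8 ± 19.0, log2 change 1.81, adjusted p = 0.0229). The list median was 0.24 (camera adjusted p = 0.197), and the list includes H1f0, a linker histone gene that is not replication-dependent. The histone list passed without a filter on low values (median 0.49, adjusted p = 0.0356), with edgeR without a filter (0.56, 0.0359) and with DESeq2 (0.56, 0.0359), with 0.393 with an estimated correlation and 0.0356 to 0.569 over the other alternatives. Its median ran 0.0345 to 0.28 with 1 library left out, lowest without taurine replicate 3. Immediate early genes went both ways, with 4 of 25 higher and 3 lower (7 and 3 adjusted over the list alone). Fosb, an AP-1 subunit (ENSMUSG00000003545.3, chromosome 7, 19302696 to 19310051, minus strand), fell from 218 ± 64.9 to 20.1 ± 10.4 (log2 change -3.49 ± 0.45 (SE), adjusted p = 0.00675), and Jun fell from 41404 ± 1245 to 33717 ± 961 (log2 change -0.30, adjusted p = 0.0192). The phosphatase gene Dusp5 (0.42) and Atf3 rose, as did Junb (0.26) and Jund (0.31), and Myc fell (-0.43), the last 3 looked up after their values were seen. The list median was -0.04 and its mean -0.20, while the test leaned upward (adjusted p = 0.544).

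Large single changes were in genes of varied function. Among called genes whose groups did not overlap, whose mean was at least 100 in the higher group and whose symbol is not a predicted or clone name, the LIM homeobox gene Lhx2 (ENSMUSG00000000247.11, chromosome 2, 38339281 to 38369733, plus strand) rose from 188 ± 23.7 to 465 ± 28.7 (log2 change 1.31 ± 0.15 (SE), adjusted p = 0.00509) and the zinc finger gene Zfp429 from 251 ± 60.0 to 692 ± 91.9 (log2 change 1.48 ± 0.19 (SE), adjusted p = 0.00675). The collagenase gene Mmp13 went from 66.4 ± 19.2 to 189 ± 49.6 (log2 change 1.49, adjusted p = 0.0242), the uridine phosphorylase gene Upp1 rose by 1.28 (adjusted p = 0.0445) and Cish, a feedback inhibitor of cytokine receptors, from 438 ± 32.2 to 1163 ± 642 (log2 change 1.28, adjusted p = 0.0449). Rnf152, Gucy2g, Unc93a and Chaf1b rose by 1.54, 1.44, 1.34 and 1.27 on the log2 scale. Fbxl2 (99.8 ± 81.9 to 329.9 ± 42.8), Rnf8 (1.46) and Rhof (1.33) complete the 12 largest rises within these limits, and their exons overlap other genes. With all reads of those genes added the changes were -0.32, -0.17 and 0.62, so their rises are uncertain. No single gene overlaps more than 11.16%, 13.18% and 11.36% of their exon length. These sums can therefore reflect the other genes' own levels and do not show that reads moved. On the other side, Lifr, a receptor for leukemia inhibitory factor, fell from 1019 ± 127 to 453 ± 52.4 (log2 change -1.17 ± 0.14 (SE), adjusted p = 0.00509) and the phospholipase-like gene Plbd1 from 507 ± 39.7 to 218 ± 28.6 (log2 change -1.22 ± 0.15 (SE), adjusted p = 0.00615). Ccdc137, Dnah6, Slc43a2, Nim1k, Chst10 and Adamts10 had log2 changes of -1.52, -1.43, -1.39, -1.29, -1.21 and -1.18. Chml and Cdc14b had -1.50 and -1.27, or -0.82 and -0.64 with the reads of overlapping genes added. The overlap covers only 6.61% and 0.12% of their exon length, so these sums can reflect the other genes' own levels. Fosb and Elovl6 complete the 12 largest falls within these limits. Outside them the clone-named C330021F23Rik, looked up after its value was seen, rose 18.2-fold, the most of any protein-coding gene. Its log2 change was 1.19 with the reads of overlapping genes added. Over all 89 called genes that the naming rules took, 33 kept their call with each library left out in turn and all 89 kept their direction. The number that kept the call was 57, 36 and 82 without R837 replicate 1, 2 or 3, and 51, 51 and 39 without taurine replicate 1, 2 or 3. With limma without the abundance trend in its variance prior all 89 lost their call.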

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

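The count models, the removal of length and GC trends and the restriction to genes without exon overlap were chosen after seeing the data. The interferon-stimulated and the cholesterol and fatty acid lists kept their direction and call under every alternative run. The number of lists past the threshold besides the interferon-stimulated one was 9, between 8 and 11 with 1 library left out, and 1 with an estimated correlation. Genes higher and lower numbered 333 and 214 with no filter on low values, where more genes share the adjustment, 1 and 3 with limma without trend, 342 and 198 with edgeR without a filter, 934 and 908 with DESeq2, and 33 and 44 with a minimum log2 change of 1; beyond the changed filters the cause was not tested. With 1 library left out they ran from 101 to 767 and from 33 to 710, with the highest of both without R837 replicate 3; the cause was not tested. No pairing of the samples is stated, and same-numbered libraries showed no shared deviation across genes, with deviation correlations of -0.00264, -0.00681 and -0.0434. These values cannot exclude a weak pairing or one that acts on few genes. A replicate block gave 365 higher and 250 lower genes. The type I and III interferon list passed with no filter (median 1.20), with fry (1.34), with edgeR without a filter (1.14) and with DESeq2 (1.07), and had too few members under the stricter filter. Its median ran from 1.11 to 1.51 with 1 library left out.

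The sums of the called genes Fbxl2 and Rnf8 with all reads of overlapping genes had the other sign, which can reflect those other genes. Apart from these sums, the lists and genes that changed sign were not called. With no filter the T and NK cell medians were 0.0313 and -0.0646, and the immediate early median was 0.00835 under the stricter filter. Quantile normalization gave -0.0434 for the TLR7 and TLR9 list, 0.0191 for cell cycle, -0.0352 for Irf5 and -0.0285 for Tnf. Rescaling without the 50 most abundant genes gave -0.0279 for the TLR7 and TLR9 list and -0.0224 for NK cells. Removal of length and GC trends gave -0.0371 for macrophages, -0.0604 for Irf5 and -0.0800 for Tnf. Genes without exon overlap gave -0.0531 for the TLR7 and TLR9 list and -0.0225 for taurine genes. The NK cell median was -0.13 with edgeR, -0.36 with edgeR without a filter and -0.36 with DESeq2, and the T cell median 0.0369 and 0.0308 with the latter pair. With 1 library left out, medians ran -0.0131 to 0.0458 for TLR7 and TLR9, -0.0575 to 0.0173 for cell cycle, -0.0588 to 0.0105 for p53, -0.0708 to 0.0387 for immediate early genes and -0.18 to 0.0196 for plasma cells. They ran -0.20 to 0.17 for T cells, -0.13 to 0.33 for NK cells and -0.15 to 0.0222 for conventional dendritic cells, and the changes of Tnf, Siglech and Csad ran -0.0364 to 0.15, -0.12 to 0.0491 and -0.15 to 0.64. The cause of these sign changes was not tested. Over all alternatives of the named genes, 2412 values kept direction and call, 405 lost the call, 58 gained it and 9 changed sign.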

Other observations

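The family tests, the removal of length and GC trends, the matched lists, the sums with overlapping genes, the overlap and marker tests and the count of splits were chosen after the values were seen. Of 13 gene families looked up by symbol, 6 passed camera and 0 with an estimated correlation. Immunity-related GTPases were the other family that passed (2 of 7 higher, adjusted p = 0.000927, or 0.332 with an estimated correlation), beside the 5 described here. The rest, from interferon-induced transmembrane genes to HSP70 and HSP40 chaperones and tRNA synthetases, had adjusted p-values of 0.0720 to 0.820. Guanylate-binding proteins, interferon-inducible GTPases of cell-autonomous defence, rose in 4 of 11 tested members and fell in 0, with a median log2 change of 0.36 (camera adjusted p = 1.87e-05, or adjusted p = 0.101 with an estimated correlation). Gbp5 went from 10356 ± 424 to 17109 ± 222 (log2 change 0.72, adjusted p = 0.00238) and Gbp2 from 19346 ± 844 to 30032 ± 1390.4 (log2 change 0.63, adjusted p = 0.00370). The p200 family of nucleic acid sensors rose in 3 of 13 (camera adjusted p = 0.000717, or adjusted p = 0.376 with an estimated correlation), with log2 changes of 0.62, 0.54 and 0.51 for the similar copies Ifi205, Ifi211 and Ifi204. Proteasome subunits rose in 12 of 41 and fell in 0 (median 0.19, camera adjusted p = 1.44e-06, or adjusted p = 0.101 with an estimated correlation), the activator subunit Psme2 among them (0.42). Of 16 actin and tubulin genes 3 rose (camera adjusted p = 0.000110, or 0.306 with an estimated correlation), with Actb going from 188901 ± 7499 to 288597 ± 22636 (log2 change 0.61, adjusted p = 0.00415), Tubb2a by 0.57 and Tubb2b by 0.56. The histone methyltransferase genes Kmt2d (18360.5 ± 622 to 12007 ± 682, log2 change -0.61, adjusted p = 0.00415), Kmt2c (-0.82) and Kmt2a (-0.37) fell among 5 Kmt2 genes (camera adjusted p = 0.000496, or adjusted p = 0.234 with an estimated correlation), whose median was -0.37 and -0.18 after removal of length and GC trends. The median of each of the 6 families that passed camera kept its sign under median ratio, quantile and abundance-trimmed scaling. Among the rest, that of the chaperones turned to -0.0201 under abundance-trimmed scaling. Under quantile normalization the schlafen median turned to -0.00614 and that of tRNA synthetases to 0.00881.

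Several abundant transcripts of these cultures belong to other cell types in common marker lists. Kdr was the 47th most abundant gene, with 48499 to 72555 normalized counts per library, and Pecam1 and Cdh5 held ranks 203 and 478. The endothelial and stromal genes Vwf, Sparc and Pdgfrb had means of 12.7, 19.2 and 10.5. Cd8a held rank 28 with a mean of 79078, beside 4505 for Cd8b1 and 1.35 for the T cell receptor subunit Cd3e. The chemokine gene Ccl22 held rank 30 and Ccr7 rank 16, ahead of Siglech at 628.

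The taurine treatment stays open as an untested explanation of each pattern that follows. A trend on transcript length and GC content ran through the comparison, and it may account for part of the rise of short housekeeping genes. With the trend removed the interferon-stimulated list had a median of 0.43, the cholesterol list -0.26, the ribosomal list 0.25 and the oxidative phosphorylation list 0.11, with adjusted p-values of 5.44e-34, 7.28e-13, 3.99e-26 and 0.000719; before removal the oxidative phosphorylation median was 0.20, and the ribosomal and oxidative phosphorylation lists did not pass with an estimated correlation (adjusted p = 0.228 and 0.228). Among 10000 lists matched on expression, length and GC, with medians between 0.15 and 0.28 for ribosomal proteins and 0.03 and 0.18 for oxidative phosphorylation, the observed medians lay at percentiles 100 and 98.8, with 100 for the interferon-stimulated and 0 for the cholesterol list. The matched lists were drawn gene by gene and hold no correlation between members, estimated at 0.577 for ribosomal proteins and 0.0854 for oxidative phosphorylation. So no verdict is drawn for these lists, though a share of their rise goes with the trend. The interferon-stimulated and cholesterol lists passed with an estimated correlation, but that test was run only before removal and does not bear on the trend. With the trend removed their medians went from 0.41 to 0.43 and from -0.35 to -0.26. Then 41 interferon-stimulated members were higher and 0 lower, and 14 cholesterol members lower and 0 higher. The fitted trend thus does not hold the whole of these shifts, though no list test with an estimated correlation was run after removal. What set the trend (RNA quality, library preparation or the taurine treatment) stays open.

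Reads that move between overlapping gene models are a candidate explanation for some of the largest values. Ifitm2 had 3149 ± 399.9 to 6874 ± 869.9 (log2 change 1.13, adjusted p = 0.00415), while Gm45717, a model whose exons overlap it, held 2723, 2817 and 2978 reads in the R837 libraries and 0 in each taurine library. With the reads of overlapping genes added, the log2 change of Ifitm2 was 0.21, so most of its rise goes with this exchange. Gm49368, another model looked up after its values were seen, held 775, 116 and 122 reads in the R837 libraries and 1, 1 and 0 in the taurine libraries. Of 5438 genes with a mean of at least 1000, 34 differed over 4-fold between libraries, and 67.6% of these overlap another gene against 38.5% of the rest (two-sided Fisher's exact p = 0.000670). These were picked for a spread between any libraries, not between the groups. Of genes called between the groups 36.5% overlap another gene, against 38.9% of all tested genes. Of 90 called genes with over 20% exon overlap, 65 kept direction and call with the reads of overlapping genes added. The losses of Gm45717 and Gm49368 run along the groups, so the R837 and taurine libraries may have been counted differently. That difference in counting or a switch of transcript form stays open.

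The rise of maturation genes such as Fscn1 and Ccr7 beside the fall of Runx2 and Tcf4 could come from a changed cell mixture, and no value here decides this. A larger share of conventional dendritic cells would raise their markers: the 16 listed markers had a median log2 change of -0.04, and 11 of them with a mean of at least 100, without Ccr7, Ccl22 and Flt3, had -0.19 (95% bootstrap interval -0.30 to 0.15). That set left out called genes, so it excludes nothing. A smaller share of plasmacytoid cells would lower their markers: 35 had a median of -0.0471 (-0.25 to 0.0624), which leaves a small fall in share open. The bootstrap intervals resample the marker genes and hold no spread between libraries. Both changes of mixture, and further maturation of the same cells with taurine, stay open.

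With 3 libraries in each group there are 10 splits, too few for a share under 0.05. The real split passed 979 genes and the highest of the others 6, and 1 of the 10 splits, the real one, gave as many. Every other split mixes the groups, so any difference between them, whatever its source, adds to the spread and lowers the count. These counts are therefore no reference for libraries without a difference.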
